A study of Rattus norvegicus with 6 samples.

How the data were processed

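Livers of 6 male Wistar Hannover rats were measured, 3 given corn oil and 3 given pregnenolone-16α-carbonitrile (PCN) at 100 mg/kg per day by gavage for 7 days, per the labels. PCN is a synthetic steroid that activates the rodent pregnane X receptor (PXR), a sensor of foreign compounds in liver. The rats were 4 weeks old when bought and were kept for 1 week before dosing. Total RNA (100 ng per sample) was labelled with the dye Cy3 and hybridised to Agilent 1-colour expression arrays, per the labels. Each array holds 62976 spots, of which 58717 are not controls, and these carry 30367 different probes.

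The deposited scanner intensity values were made with Agilent Feature Extraction 10.7.3.1, per the file headers, under its 1-colour gene expression protocol. The intensity used here is the processed signal, which per the file headers is background-subtracted within the array and not scaled between arrays. The deposited files also carry quality marks of other kinds for each spot (well above background, saturated, non-uniform, population outlier), set by the scanner software per the file headers. The authors also deposited a table of values, compared here with the scanner values. By this comparison the deposited values are a linear ratio made by the authors, the processed signal of a spot divided by the 75th percentile of its array, given to 2 decimals, with no centring of genes. Over the brighter non-control spots, its columns correlated with the scanner values at 0.99999 or more on the log scale. Spots of low signal, the larger part of each array, were left out of this. Up to 23.7% of the deposited values of an array were 0. The medians of the columns were 0.09 on the control arrays and 0.08 on the PCN arrays. How the authors tested for changed genes is not given in the sources used here. The files name the rat build rn4, and the table used here for gene names belongs to the assembly GRCr8, so no coordinates are given.

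From the intensities, log2 processed signal minus the 75th percentile of the array over non-control spots was computed in R 4.3.3 with data.table version 1.17.8. Control spots and spots marked as outliers were left out, spots of 1 probe were averaged, and 14 probes lost every spot on some array. A probe was tested if it was well above background on all 3 arrays of at least 1 group, which kept 18329 probes. Probes were named through their transcript accession: 18004 of 30367 probes matched exactly 1 gene symbol, and the others kept the name in the file. A gene with several tested probes was represented by the brightest one, giving 16389 tested genes and features, 10044 with a symbol and 6345 without. Of 1785 genes with several tested probes, 6 had probes called in opposite directions. For brevity, genes and features without a symbol are both called genes in counts over all of them.

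The groups were compared with limma 3.58.1 (lmFit and eBayes, both groups in 1 fit, no covariate, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and, for a second count, at least a 2-fold change. Values are log2 fold changes, PCN minus control, with their standard error (SE) from 3 arrays per group. Where a gene was not well above background on any array of a group, a bound is given as "at least N-fold": the mean of the bright group against the mean, in the dim group, of the higher of the probe's own signal and the lowest signal of a probe well above background on that array. Where the probe's own signal is the higher on each array, this bound equals the measured change. It is not a confidence limit, and it holds for the main scaling only. The number of arrays limits the precision of each value. The labels call the samples biological replicates, and the design text gives 3 rats per group.

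43 gene lists were written from textbook knowledge: drug metabolism, conjugation, transport, lipid, glucose, stress, clock and hormone lists, and markers of other cell types. The 38 lists with at least 5 tested members were tested with camera (preset correlation 0.01), and their adjusted p covers those 38 tests. Camera asks whether a list moved relative to the other genes. Counts of members were also made with p adjusted over the list alone. Percentiles of a list's median come from 10000 random lists matched on brightness. The genes named are the 10 largest rises and 10 largest falls past the threshold with all PCN arrays beyond all control arrays and an official-style symbol, a set of genes of PXR biology named whatever their values, and up to 4 members of each list past the test (up to 2 with none past it). Any other gene named is said to have been chosen after its value was seen. These lists, rules and tests, and the alternatives below except those said to be added, were fixed before the data were examined.

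The alternatives were quantile normalization, median scaling, normexp background correction (offset 50), the deposited value table, no filter on dim probes, a filter to probes well above background on all 6 arrays, spots marked as outliers kept, the mean of a gene's probes, each probe by itself, eBayes with trend and robust, array weights, the replicate number as a block, adjusted p under 0.01, at least a 1.5-fold change, camera with an estimated correlation, fry, and each array left out in turn. Normexp was planned on the mean spot signal. The files used here carry the median spot signal, which took its place. Cyclic loess normalization and scaling to the E1A spike-in probes were added after seeing the data. The tests were tested on simulated data with the spread of these arrays (16389 genes, 200 changed, 20 simulations of PCN against control): 4.93% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 91.9% of those changed 4-fold were found, and 4.33% of calls were false. A simulated list of 24 genes shifted by 0.5 on the log2 scale was called in 20 of 20 simulations, and 0 of 600 unshifted lists were. These simulated genes varied independently of each other. Far fewer of them changed than passed the test in the real data (3263), which makes the adjusted threshold stricter. The rates found are therefore not those of the real comparison.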

Results

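The data are 6 expression arrays of rat liver, 3 from rats given corn oil (control) and 3 from rats given PCN for 7 days. The 75th percentile of the processed signal was 678, 758 and 634 on control arrays 1 to 3 and 594, 627 and 488 on PCN arrays 1 to 3. Between 65.5% and 68.9% of spots lay well above background on the control arrays and between 61.6% and 65.8% on the PCN arrays, and 0 spots were saturated. Arrays of 1 group correlated at 0.990 to 0.993 over genes, arrays of different groups at 0.975 to 0.981, and the first principal component, with 64.6% of the variance, separated the groups. The control arrays lay on 1 slide and the PCN arrays on another, each with its own scan, so slide and treatment cannot be told apart.

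The comparison asks which liver transcripts differ after repeated dosing with a PXR activator. Transcripts of several drug-metabolizing enzymes and transporters were higher with PCN, among them Cyp3a23-3a1, the inducible cytochrome P450 of the 3A subfamily, which rose 19.8-fold (log2 4.31 ± 0.19 SE, n = 3 per group, adjusted p = 1.69e-04). Slco1a4, an uptake transporter of organic anions, rose 10.6-fold (3.41 ± 0.22, adjusted p = 3.56e-04). The bile acid and steroid sulfotransferase Sult2a2 rose by 4.84 ± 0.71 on the log2 scale, and Gadd45b, a stress-inducible gene, by 3.76 ± 0.17 (adjusted p = 6.13e-03 and 1.69e-04). Among genes with a symbol, Akr1b7, an aldo-keto reductase, fell by 4.26 ± 0.75, and Shox2, a homeobox gene not well above background on any PCN array, was at least 10.9-fold lower (adjusted p = 0.0111 and 3.66e-03). All 3 PCN arrays lay beyond all 3 control arrays for each of these genes, as the rule for the largest rises and falls required.

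In all, 3263 of 16389 tested genes passed the test, 716 higher and 2547 lower with PCN. With at least a 2-fold change there were 1315, of which 126 were higher and 1189 lower, against 425 with normexp (84 and 341) and 2228 with spike-in scaling. Without adjustment 5653 genes had p under 0.05, and in 6781 (41.4%) the groups did not overlap, where chance gives 10%. Of the genes past the test 78.1% were lower, against 65.9% with quantile normalization, 41.0% with median scaling, 61.3% with cyclic loess and 96.6% with scaling to the E1A spike-ins, the last pair chosen after seeing the data. Among genes changed at least 2-fold the shares were 90.4%, 84%, 79%, 79.8% and 96.2% in the same order, and 80.2% with normexp. The median log2 fold change of all tested genes was −0.06, and 0.14 and −0.32 under median and spike-in scaling. The count was 2023, 2112 and 2048 without control replicate 1, 2 and 3, and the number of genes higher was then 308, 375 and 291, and 454 and 407 without PCN replicate 1 and 3.

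Of 38 gene lists tested, 7 passed upward and 1 downward, and 0 passed with an estimated correlation. Another split of the 6 arrays into 3 and 3 gave as many as 12, but keeps part of the treatment difference, so it decides nothing. The upward lists are not separate responses, since several share tested members with the PXR and CAR list. These are 7 P450s, 2 glutathione S-transferases, 2 male-biased genes, 1 UDP glucuronosyltransferase and 1 NRF2 gene. Most genes known to respond to PXR and the related receptor CAR rose. Of 24 tested members, 17 rose, 1 fell and 6 did not pass (19 and 1 adjusted over the list alone), with a median log2 fold change of 1.42. The list passed the camera test (adjusted p = 1.38e-14), and had adjusted p = 0.192 with an estimated correlation. Cyp3a18 rose 8.58-fold, Cyp3a9 9.27-fold (log2 3.21 ± 0.32) and Cyp2b2, the phenobarbital-inducible P450, 6.26-fold (2.65 ± 0.23; adjusted p = 1.77e-04, 1.49e-03 and 9.55e-04), its other probe giving 1.54. Cyp3a2, already abundant in controls, rose by 0.89 ± 0.10 (adjusted p = 2.41e-03). Por, the electron donor of microsomal P450s, rose by 1.21 ± 0.13 (adjusted p = 2.20e-03), and the epoxide hydrolase Ephx1 by 1.64 ± 0.27 (adjusted p = 8.92e-03). Alas1, the rate-limiting enzyme of heme synthesis, rose by 1.44 ± 0.39 (adjusted p = 0.0437), and lost this call without any 1 of control replicates 1 to 3 or PCN replicates 2 and 3 (adjusted p = 0.127, 0.0613, 0.121, 0.0975 and 0.0622). The member that fell was Akr1b7. Over the P450 families 1 to 4 as a whole, 10 of 42 rose and 4 fell (10 and 5 adjusted over the list alone), with a median of 0.04 that turned to −0.22 under spike-in scaling. The list test gave adjusted p = 0.0138 upward, and adjusted p = 0.622 with an estimated correlation. That call also ended with quantile normalization (adjusted p = 0.266). The alternatives ranged from 5.83e-05 to 0.622, the lowest from the mixed form of fry, which lets members go both ways and is no test of a rise. Cyp2c11, the main male-specific P450, gave 0.33 ± 0.19 (adjusted p = 0.281), and Cyp1a2 fell by 1.39 ± 0.27 (adjusted p = 0.0149), a call lost without control replicate 1 or 2 (adjusted p = 0.0516 and 0.0502).

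**Figure D1:**
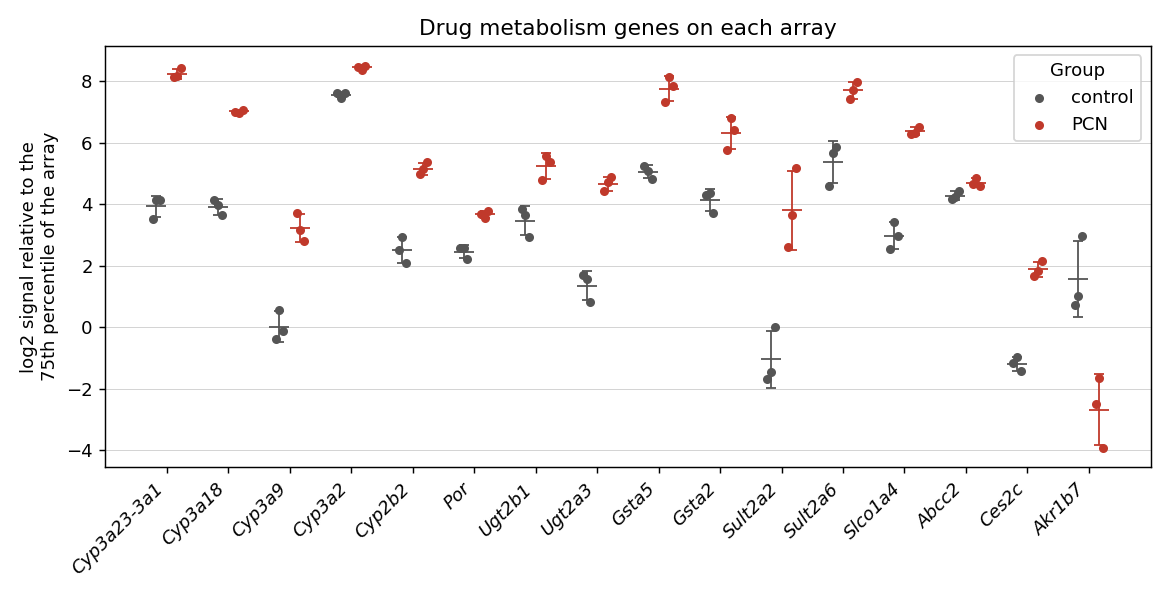
Log2 signal relative to the 75th percentile of the array (vertical axis) for 16 genes of drug metabolism on each of the 6 arrays, with control arrays in grey and PCN arrays in red; horizontal ticks are group means and whiskers 1 SD. Cyp3a23-3a1 moves from a mean of 3.94 to 8.25, while Akr1b7 falls from 1.58 to −2.68.

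Conjugating enzymes rose in part. Among glutathione S-transferases 7 of 24 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.15 that turned to −0.11 under spike-in scaling. Their list test gave adjusted p = 7.07e-04, and adjusted p = 0.410 with an estimated correlation. Gstm3 rose by 3.69 ± 0.62, Gsta5 by 2.71 ± 0.22, Gsta2 by 2.19 ± 0.29 and Gstm2 by 1.71 ± 0.20. The member that fell was Mgst3 (by 1.26 ± 0.26), named after its value was seen. Of 9 UDP glucuronosyltransferases 3 rose and 0 fell, also adjusted over the list alone: Ugt2a3 by 3.32 ± 0.25, Ugt2b1 by 1.78 ± 0.30 and Ugt1a6 by 1.35 ± 0.13 (1.94 at its other probe). Their median was 0.31 (0.06 at the lowest over the alternatives), with adjusted p = 1.21e-03, and adjusted p = 0.588 with an estimated correlation. Among 8 sulfotransferases 3 rose and 0 fell (3 and 1 adjusted over the list alone). These were Sult2a2, Sult2a6 (by 2.34 ± 0.34) and Sult1b1 (by 1.08 ± 0.15), and Sult2a1 gave 0.30 ± 0.26 (adjusted p = 0.474). Their median of 0.18, which turned to −0.08 under spike-in scaling, did not pass the list test (adjusted p = 0.0655). The carboxylesterases split, 2 of 13 rising and 2 falling (4 and 3 adjusted over the list alone; list adjusted p = 0.466). Ces2c and Ces2j rose by 3.08 ± 0.17 and 3.01 ± 0.19, and Ces1a and Ces5a fell by 1.17 ± 0.11 and 0.80 ± 0.14. The call for Ces5a ended with cyclic loess, with normexp and with spots marked as outliers kept (adjusted p = 0.123, 0.877 and 0.0700). Aldehyde dehydrogenases also split, 3 of 14 higher and 3 lower, also adjusted over the list alone, with Aldh3b1 and Aldh1a1 up by 1.91 ± 0.37 and 1.39 ± 0.22 (list adjusted p = 0.181).

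Transporters of bile acids and drugs moved in both directions, 6 of 23 rising and 2 falling (7 and 2 adjusted over the list alone). Besides Slco1a4, the sterol exporter subunit Abcg5 rose by 2.69 ± 0.18 (adjusted p = 3.58e-04) and the efflux pump Abcb1a by 1.40 ± 0.25 (adjusted p = 0.0108). The related Abcb1b, named after its value was seen, gave 0.02 ± 0.11 (adjusted p = 0.916). Its mean log2 signal in controls was 2.61, against −3.80 for Abcb1a. Abcc3, not well above background on any control array, rose at least 5.40-fold (adjusted p = 0.0151), while Abcc2 gave 0.43 ± 0.13 (adjusted p = 0.0564). The 2 that fell were the carnitine transporter Slc22a5 (by 0.96 ± 0.17) and Abcg2 (by 0.79 ± 0.21), both named after their values were seen. The median of the list was −0.10, while its mean (0.36) and the direction of its test were upward, and it did not pass (adjusted p = 0.118).

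Cholesterol synthesis genes rose in part: 8 of 23 rose and 1 fell, also adjusted over the list alone. The median was 0.32 (0.07 at the lowest over the alternatives), with adjusted p = 6.25e-04, and adjusted p = 0.192 with an estimated correlation. Sqle, which catalyses the first oxygenation step, rose by 1.44 ± 0.27 and Idi1 by 1.31 ± 0.24 (adjusted p = 0.0127 and 0.0120). Insig1, a brake on sterol synthesis, fell by 1.35 ± 0.34 (adjusted p = 0.0350), and 5 of 6 fits with 1 array left out did not call it (adjusted p = 0.0522 to 0.0929, all but that without PCN replicate 3). In bile acid synthesis 1 of 14 rose and 0 fell, and 0 were called adjusted over the list alone, with Cyp7a1, its rate-limiting enzyme, at −0.54 ± 0.76 (adjusted p = 0.662; list adjusted p = 0.0855). That member was Cyp39a1, at 0.41 ± 0.11 (adjusted p = 0.0409), not called in any fit with 1 array left out (adjusted p = 0.061 to 0.120). Cyp7a1 was well above background on 1 of 3 PCN arrays. Its change ranged from −1.37 to 0.11 over the alternatives, so whether it changed is not settled.

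Other parts of liver metabolism changed at few members, and none of these lists passed its test. In fatty acid and triglyceride synthesis 0 of 18 rose and 3 fell (also adjusted over the list alone): Elovl5 by 1.23 ± 0.16, Dgat2 by 0.51 ± 0.14 and Thrsp (list adjusted p = 0.876). Thrsp, a thyroid hormone responsive regulator of lipid synthesis, fell by 0.93 ± 0.23 (adjusted p = 0.0346), and was not called without control replicate 1 or 2 or PCN replicate 1 or 3 (adjusted p = 0.0946, 0.0875, 0.0841 and 0.0785). In fatty acid oxidation 2 of 27 rose and 3 fell (2 and 4 adjusted over the list alone), with Cyp4a8 and Angptl4 down by 0.92 ± 0.17 and 0.71 ± 0.13 (list adjusted p = 0.859). In gluconeogenesis 0 of 12 rose and 2 fell (also adjusted over the list alone), Pc, pyruvate carboxylase, by 0.74 ± 0.13 and the coactivator Ppargc1a by 1.62 ± 0.41 (list adjusted p = 0.555). Of 16 apolipoprotein and lipoprotein genes 1 rose and 1 fell (also adjusted over the list alone), Apoa2 by 0.82 ± 0.19 and the HDL receptor Scarb1 by 1.23 ± 0.12 (list adjusted p = 0.324). The urea cycle and amino acid list (0 of 17 past the test, list adjusted p = 0.322), acute phase proteins (0 of 17, 0.514) and coagulation factors (0 of 11, 0.876) held no called member, nor did any of them adjusted over the list alone. In heme synthesis 2 of 8 rose, also adjusted over the list alone, Alas1 and Alad (by 0.48 ± 0.10; list adjusted p = 0.0655). Dgat2, Ppargc1a, Apoa2 and Alad each lost the call in 4 or 5 of 6 fits with 1 array left out, at adjusted p of up to 0.115, 0.0908, 0.0785 and 0.0622. The change of Ppargc1a ranged from −2.04 to −0.48 over the alternatives.

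Cell cycle genes fell in part. Of 28 tested members 13 fell, 1 rose and 14 did not pass (15 and 1 adjusted over the list alone), with a median of −0.73. The list test gave adjusted p = 8.48e-04, and adjusted p = 0.622 with an estimated correlation. The transcription factor Mybl2 and the mitotic cyclin Ccnb2, not well above background on any PCN array, were at least 7.65-fold and at least 2.87-fold lower (adjusted p = 1.70e-03 and 8.60e-03), and Ccna2 fell by 1.42 ± 0.19 (adjusted p = 4.16e-03). The member that rose was Tk1 (0.50 ± 0.11, adjusted p = 0.0206), named after its value was seen. With normexp the median was −0.14, Mybl2 gave −0.61, and Ccnb2 and Ccna2 were not called (adjusted p = 0.720 and 0.0711). Markers of other cell types were measured beside them. Of 12 Kupffer cell markers 0 passed the test, with a median of −0.38 (list adjusted p = 0.181), and of 6 T cell markers Lck and Cd3d fell, Lck turning to 0.06 with normexp, with a median of −0.49 (list adjusted p = 0.324). Of 14 stellate cell markers 1 rose and 2 fell (median −0.06, list adjusted p = 0.913), Rgs5 rising by 0.96 ± 0.17, and Acta2 and the retinol esterifying enzyme Lrat falling by 0.74 ± 0.16 and 1.33 ± 0.22. Of 8 endothelial markers Cdh5 fell, and 2 were called adjusted over the list alone (median −0.12, list adjusted p = 0.714). Of 5 neutrophil markers Fcnb fell (list adjusted p = 0.512), and of 6 red blood cell markers 0 passed (list adjusted p = 0.729). For T cell, stellate, neutrophil, Kupffer and red blood cell markers the counts were the same adjusted over the list alone. Lck, Acta2, Cdh5 and Fcnb lost the call in 4 to 6 of 6 fits with 1 array left out (adjusted p of up to 0.0688, 0.0755, 0.134 and 0.128).

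Antioxidant genes driven by NRF2 moved both ways, 4 of 21 rising and 2 falling (6 and 2 adjusted over the list alone), with a median of 0.25 that turned to −0.01 under spike-in scaling. The list test gave adjusted p = 8.34e-03, and adjusted p = 0.622 with an estimated correlation. It was not past the threshold with quantile normalization (0.075), median scaling (0.081) or without PCN replicate 2 (0.0805), the alternatives ranging from 1.46e-05 to 0.622. Gsr, glutathione reductase, rose by 1.29 ± 0.21 (adjusted p = 8.93e-03), and Gclm, a subunit of the enzyme that starts glutathione synthesis, fell by 2.40 ± 0.66 (adjusted p = 0.0457). Gclm was well above background on 1 of 3 PCN arrays, and gave −0.26 with normexp (adjusted p = 0.121). It was called in 1 of 6 fits with 1 array left out, that without PCN replicate 2, the others giving adjusted p = 0.0875 to 0.134.

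Genes with sex-biased expression in rat liver also moved. Of 12 male-biased genes 5 rose and 0 fell (5 and 1 adjusted over the list alone), with a median of 0.41, adjusted p = 7.07e-04, and adjusted p = 0.382 with an estimated correlation. Of these, Cyp3a18 and Cyp3a2 also belong to the PXR list, and Cyp2a2 rose by 1.05 ± 0.18 (adjusted p = 0.0105). Of 8 female-biased genes 4 rose and 2 fell, also adjusted over the list alone (median 0.33, list adjusted p = 0.322), with Sult2a2 and Sult2a6 among the rises and the prolactin receptor Prlr falling by 1.45 ± 0.26 (adjusted p = 0.0111). The receptors themselves gave −0.10 ± 0.11 for Nr1i2, which encodes PXR, and −0.33 ± 0.38 for Nr1i3, which encodes CAR (adjusted p = 0.561 and 0.580). Among 20 nuclear receptors and sensors 2 rose and 2 fell, also adjusted over the list alone (list adjusted p = 0.322). Thrb, a thyroid hormone receptor, rose by 0.88 ± 0.15 and Hnf4a by 0.63 ± 0.13, and Nr0b2, a repressor of bile acid synthesis, fell by 1.66 ± 0.44 (adjusted p = 0.0108, 0.0160 and 0.0425). Nr3c1, the glucocorticoid receptor, fell by 0.55 ± 0.12 (adjusted p = 0.0235) at its brighter probe, while its other probe gave 0.01. Hnf4a was not called without control replicate 3 (adjusted p = 0.0565), nor Nr3c1 without control replicate 2 or 3 or PCN replicate 1 or 3 (adjusted p = 0.0750, 0.0786, 0.0675 and 0.0627). Nr0b2 was not called without control replicate 1 or 3 or PCN replicate 1 or 2 (adjusted p = 0.113, 0.116, 0.105 and 0.0961).

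**Figure D2:**
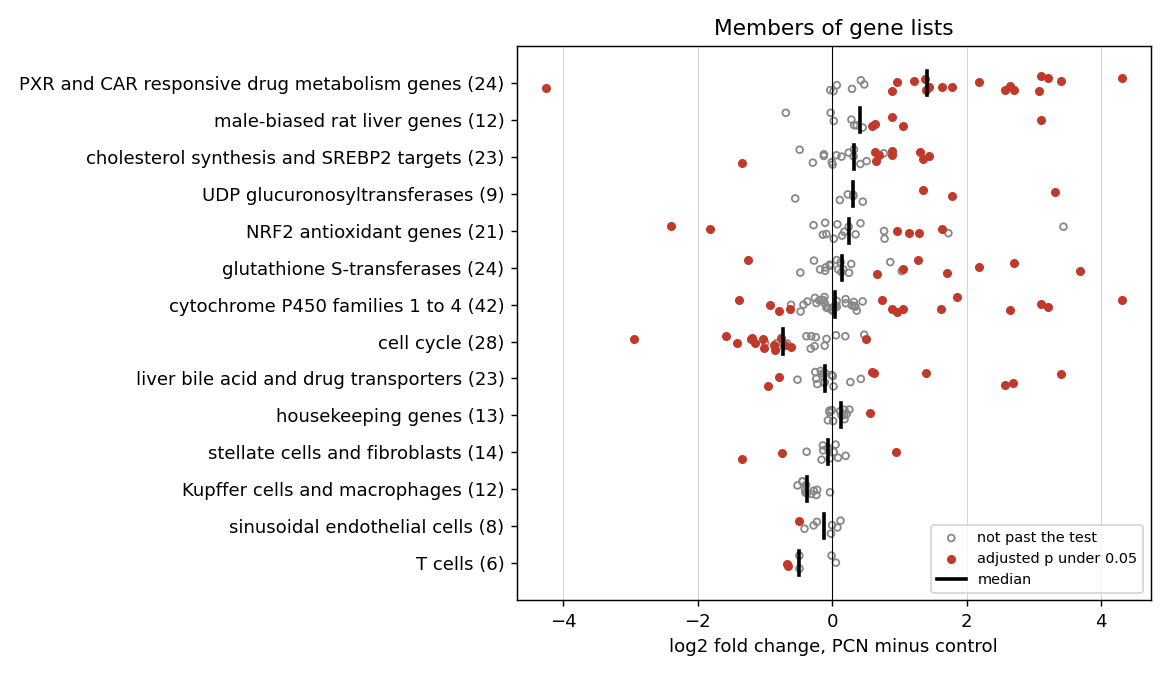
Log2 fold change, PCN minus control (horizontal axis), of each tested member of 14 gene lists, with the number of members in brackets; filled points have adjusted p under 0.05 and black bars are list medians. The 24 PXR and CAR responsive genes have a median of 1.42 and the 28 cell cycle genes of −0.73; under spike-in scaling the medians of the P450, glutathione S-transferase and NRF2 lists turn to −0.22, −0.11 and −0.01.

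The remaining lists did not pass their test. Of 5 thyroid hormone responsive genes Thrsp and Gpd2 fell (list adjusted p = 0.322), of 10 p53 targets Ccng1 and Aen fell and 4 were called adjusted over the list alone (0.322), of 15 immediate early genes Gadd45b rose and Fosb fell (0.859), and of 13 clock genes Bhlhe40 fell (0.729). The unfolded protein response (0 of 19 past the test, 0.790), interferon-stimulated genes (0 of 13, 0.466) and periportal hepatocyte markers (0 of 10, 0.714) held no called member, and of 8 pericentral markers Cyp1a2 and Glul fell (0.653). Gpd2, Ccng1, Aen, Fosb, Bhlhe40 and Glul lost the call in 3 to 5 of 6 fits with 1 array left out (adjusted p of up to 0.0594, 0.104, 0.129, 0.0911, 0.0773 and 0.119). Of 13 housekeeping genes Hprt1 rose by 0.56 ± 0.11 (adjusted p = 0.0154; list adjusted p = 0.0655), and it was not called under spike-in scaling (adjusted p = 0.202) or without control replicate 1 or 3 (0.0513 and 0.0590). Except for p53 targets, counts adjusted over the list alone were the same. Lists with fewer than 5 tested members were only counted: of 3 AHR targets 2 rose and 1 fell, of 4 cholangiocyte and 4 B cell markers 0 passed, the 1 pancreatic marker, Ctrb1, fell by 0.78 ± 0.17, a call lost in 4 of 6 fits with 1 array left out (adjusted p of up to 0.0742), and the 1 adipocyte marker, Cidec, gave −0.44 ± 0.16 (adjusted p = 0.103, called adjusted over the list alone). Besides the transporters, the signs of median, mean and test differed for carboxylesterases (−0.03, 0.33, upward), immediate early genes (−0.31, 0.04, upward) and nuclear receptors (0.03, −0.05, upward). Median and mean were below 0 with an upward test for fatty acid oxidation (−0.02 and −0.16), acute phase proteins (−0.00 and −0.10), coagulation factors (−0.04 and −0.05) and periportal markers (−0.04 and −0.21).

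Among other single genes, Cda, cytidine deaminase, was not well above background on any control array and rose at least 17.4-fold (adjusted p = 5.72e-04), and Dnajb3, a co-chaperone, rose by 3.85 ± 0.18 (adjusted p = 1.77e-04; 3.00 at its other probe). With normexp the rises of Cda, Dnajb3 and Abcc3 were 1.495, 1.82 and 0.76 on the log2 scale. Cyp26b1, a retinoic acid hydroxylase, was at least 10.3-fold lower, Rasd2 at least 5.13-fold, Ly6al 7.31-fold and the odorant receptor Or8g36b at least 5.71-fold (adjusted p = 4.09e-03, 1.56e-03, 0.0134 and 0.0121). For Ly6al the bound was the measured change itself (−2.87 ± 0.54 on the log2 scale). Slc34a2, a phosphate transporter, fell by 3.35 ± 0.35, Pcyox1l by 2.72 ± 0.29 and Taar8c, a trace amine receptor, by 2.61 ± 0.62 (adjusted p = 1.87e-03, 2.10e-03 and 0.0297). Slc34a2 was well above background on 1 of 3 PCN arrays, and its change was −0.96 with normexp. Taar8c was not called without PCN replicate 1, 2 or 3 (adjusted p = 0.0651, 0.0816 and 0.0726), and with normexp Taar8c, Shox2, Ly6al and Or8g36b were not called (adjusted p = 0.104, 0.0711, 0.121 and 0.143). With normexp Cyp26b1 and Rasd2 gave −1.01 and −0.42. Cyp1a1 was not well above background on all arrays of either group, and Cyp2b1, Ugt1a1 and Mki67 had no probe under those symbols.

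The falls lay mostly among dim genes. With the tested genes split by signal into 4 equal classes, 92.3%, 83.3%, 67.1% and 52.2% of the genes past the test were lower, from the dimmest class to the brightest, and the median log2 fold changes were −0.36, −0.09, −0.00 and 0.04. With quantile normalization 67.9% were lower in the dimmest class and 64.2% in the brightest. Of the genes past the test, 264 were not well above background on any PCN array and 11 on any control array.

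**Figure D3:**
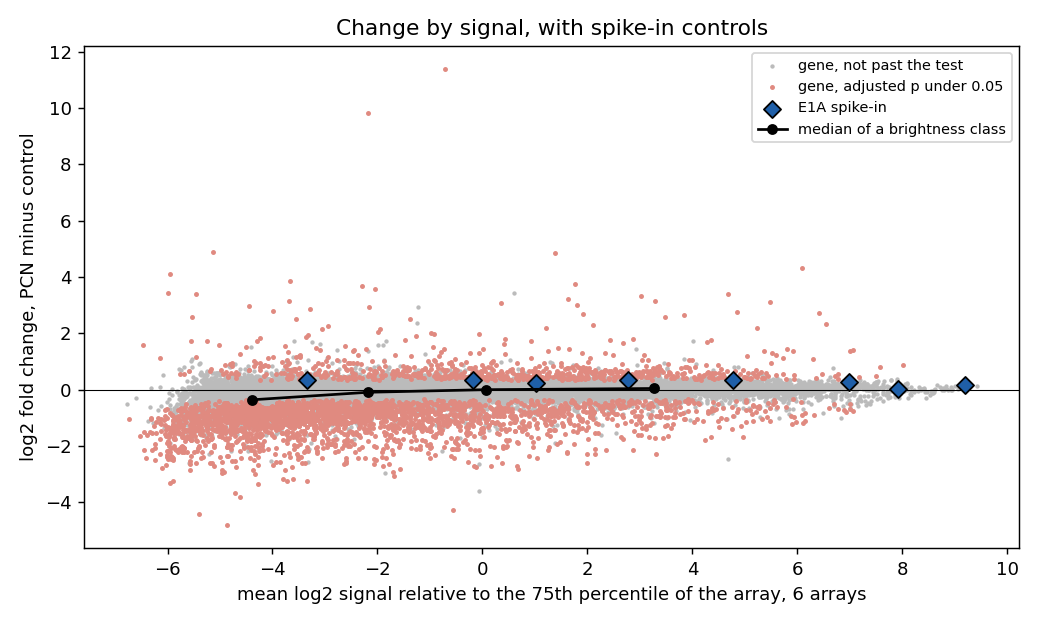
Log2 fold change, PCN minus control (vertical axis), against the mean log2 signal relative to the 75th percentile of the array (horizontal axis) for 16389 genes; red points have adjusted p under 0.05, black circles are medians of 4 equal brightness classes and blue diamonds the 8 E1A spike-in probes above background. The medians run from −0.36 in the dimmest class to 0.04 in the brightest, while the spike-in probes lie between 0.03 and 0.35.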

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

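The tests on the surplus of falling genes were chosen after the counts of rising and falling genes were seen, but before the values they measure. An exception is the test on vomeronasal, taste and trace amine receptor genes, given further below, which is recorded as written after. A signal outside the main measurement differed between the groups after scaling. The E1A spike-in probes are made to report control RNA added in fixed amounts. After scaling, 8 of 10 were above background and higher on the PCN arrays, by a median of 0.302 on the log2 scale (range 0.03 to 0.35). In 6 of 8 the groups did not overlap. The unscaled differences of these 8 probes ran from −0.255 to 0.06, with both signs, so the shift came with the scaling. Before scaling, the 75th percentile of the processed signal was lower on each PCN array (488 to 627) than on each control array (634 to 758).

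With the main scaling more genes fell than rose, and a loss of dim signal on the slide that held the PCN arrays stays open. After scaling, the dim spike-in probe was 0.33 higher on that slide (SE 0.10), where 1000 genes of like brightness had a median of −0.18. Without scaling this probe was 0.05 higher. It is 1 probe, and it is brighter than the median of the dimmest of 4 equal classes of genes. The slides also differed at the dim end, with a median background of 37 to 39 on the control arrays and 26 to 30 on the PCN arrays, and with 7.02% to 11.1% against 2.89% to 4.40% of spots of ERCC probes, which match no rat gene, above background. Scaling and signal near background each may account for part, and cannot be told apart from a true surplus: 65.9% of called genes were lower with quantile normalization, and 60.1% among genes brighter than the median gene, both between the limits set in advance. With median scaling 41.0% of called genes were lower, so the direction of the surplus depends on the scaling. Among genes changed at least 2-fold, 79% were lower with median scaling. A treatment effect and a difference in RNA or labelling between the groups are also open, since each group lay on 1 slide. The 10 splits of 6 arrays into 3 and 3 are too few to reach a share under 0.05: the real split gave 3263 genes and 1315 with at least a 2-fold change, the highest of the others 0 and 0, so 1 of 10 splits reached each count. Each other split mixes control and PCN arrays, so the difference between them adds to the spread within its groups and works against calls. The counts of 0 are therefore no measure of chance.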

How the results depend on the processing

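Cyclic loess and spike-in scaling were chosen after seeing the data; slide as a block was not run, since each group lies on its own slide, and the cause was not tested for any of these changes unless fewer samples or another threshold made them. Counts kept within 1.5 times of the main count in 114 of the recomputed counts, and moved in 37. Against 3263 changed genes (716 higher, 2547 lower), no filter on dim probes gave 1967 (283 and 1684), adjusted p under 0.01 gave 1191 (156 and 1035), and spike-in scaling gave 4992 (168 and 4824). Median scaling gave 2686 higher, cyclic loess 1153 higher and normexp 1432 lower. Against 1315 genes changed at least 2-fold (126 higher, 1189 lower), normexp gave 425 (341 lower), adjusted p under 0.01 gave 797 (78 and 719), a 1.5-fold threshold 2573 (359 and 2214) and spike-in scaling 2228 (2143 lower); median scaling gave 215 higher, probes well above background on all 6 arrays 783 lower, and cyclic loess 741 lower. With 1 array left out 2023 to 2592 genes changed, 291 to 543 higher. The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at −0.10, −0.03 and −0.05, and with the replicate block 2067 genes were called, 306 of them higher. Among named genes, calls ended in 255 cases and appeared in 31, and 34 of 91 called genes lost the call without at least 1 array; Lck reversed to 0.058 with normexp. Of gene list results 779 stayed on the same side of the threshold, most of them lists not called in either setting, 19 lost a call, 33 gained one and 4 reversed. With an estimated correlation 0 lists passed, at unchanged medians of 1.42 (PXR and CAR), 0.038 (P450), 0.31 (UDP glucuronosyltransferases), 0.15 (glutathione S-transferases), 0.32 (cholesterol), −0.73 (cell cycle), 0.25 (NRF2) and 0.41 (male-biased). The P450 list was also not called with quantile normalization (median 0.014), median scaling (0.24), normexp (0.053), no filter (0.025), cyclic loess (0.041) or directional fry (0.038), and the NRF2 list with quantile normalization (0.25), median scaling (0.45), cyclic loess (0.29), directional fry (0.25) or without PCN replicate 2 (0.12, the others to 0.39). Under spike-in scaling the medians reversed to −0.22 (P450), −0.11 (glutathione S-transferases), −0.083 (sulfotransferases) and −0.012 (NRF2), each still above the other genes by camera (adjusted p = 6.43e-05, 1.22e-06, 9.28e-04 and 1.46e-05). Transporters (−0.36) and female-biased genes (0.076) were also called under that scaling. In the main fit the camera direction of both was upward. Sulfotransferases were called with the replicate block, directional and mixed fry (0.18) and without control replicate 3 (0.32, range over left-out arrays 0.087 to 0.35), and bile acid synthesis with mixed fry (0.12) and without PCN replicate 2 (0.16, the others from 0.095). Fry called transporters in both forms, upward in its directional form (adjusted p = 6.47e-03) though their median was −0.10. Its mixed form, which lets members go both ways, also called fatty acid synthesis (−0.017), fatty acid oxidation (−0.024), gluconeogenesis (−0.25) and female-biased genes (0.33), 29 lists in all. Signal over background limits the dim genes: with normexp, which adds an offset, changes of genes near background shrink in both directions.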

Other observations

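The gene families and probes in these paragraphs, the genes named from them, and the tests on them, on cell cycle genes and on PXR genes were chosen after the main comparison was seen. Of 33 tested proteasome subunits 23 rose, 0 fell and 10 did not pass, 3 of these lying below 0. The median log2 fold change was 0.50, above each of 10000 random lists of like brightness (middle 95% from −0.07 to 0.14), which leave out correlation between members; camera with an estimated correlation gave p = 0.0423, not adjusted for the choice of this family. Psmc4, an ATPase of the regulatory particle, rose by 0.87 ± 0.13, Psmb3 by 0.81 ± 0.13 and Psmd14, its deubiquitinase, by 0.75 ± 0.13. Between 20 and 28 members rose with quantile, median, normexp and cyclic loess settings, and 1 rose and 1 fell under spike-in scaling, where the median was 0.24. Among 7 organic anion transporters of the Slco family 4 rose and 0 fell (median 0.59), against 3 and 1 under spike-in scaling. Among 80 ribosomal protein genes 0 rose and 1 fell, and among 31 subunits of NADH dehydrogenase 0 rose and 1 fell, while 14 and 8 rose under median scaling. Of 14 collagens 0 rose and 3 fell, and of 31 ABC transporters 5 rose and 1 fell, against 3 and 5 under spike-in scaling. Of 32 potassium channels 1 rose and 12 fell, and 4 fell with normexp.

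A pair of features without a gene symbol rose more than any named gene. The probe A_64_P132261 was at least 2566-fold higher and the probe A_64_P030504 at least 727-fold higher with PCN (adjusted p = 1.69e-04 for each), neither being well above background on any control array.

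Odorant receptor genes, whose known site of use is the nose, were lower. Of 88 tested members 60 fell and 0 rose, with a median of −1.09, below each of 10000 random lists of like brightness (middle 95% from −0.62 to −0.27), while camera with an estimated correlation gave p = 0.093. Their median log2 signal was −4.31, −4.01 and −4.42 on control arrays 1 to 3 and −5.00, −5.48 and −4.91 on PCN arrays 1 to 3. With normexp 14 fell and the median was −0.12, with cyclic loess 42 (−0.77) and with quantile normalization 50 (−0.83). Cyclic loess brought the median of the dimmest of 4 equal classes of genes to −0.00. Genes were tested if well above background on all arrays of at least 1 group. Many odorant receptors met that only on the control arrays, and Or10al27 only on the PCN arrays. Such a filter favours falls, so the count and the median rest in part on it. Among the falls were Or10ak14 and Or6d14, not well above background on any PCN array (adjusted p = 8.13e-04 and 6.42e-04). A hypothesis is that the control RNA carried more signal from sequence that liver does not use as transcripts, such as DNA or unspliced RNA. It needs other sensory receptor genes to fall alike. The 18 vomeronasal, taste and trace amine receptor genes tested had a median of −1.11, with 15 lower and 0 higher. The median was −0.19 with normexp (5 lower), −0.83 with cyclic loess (9 lower) and −0.91 with quantile normalization (11 lower). This may fit, though a fall of dim signal of any other source in the samples would give it too. The filter favours falls here as well, and 1 member, Taar8c, had been seen before the test. Unlike the other tests on falling genes, this one is recorded as written after, so it is not a prediction made in advance. Binding of unrelated labelled RNA was tested with 96 ERCC probes, which match no rat gene. Their median difference was 0.15, but 6.42% of their spots lay above background, so the median decides nothing. The share above background was 9.32%, 11.1% and 7.02% on control arrays 1 to 3 and 4.40%, 3.78% and 2.89% on PCN arrays 1 to 3, which goes with more unspecific signal, or another reading of background, on the control slide, so this stays open.

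The median of the cell cycle list lay at percentile 0 of random lists of like brightness (middle 95% from −0.45 to −0.01), and with normexp, where it shrank from −0.73 to −0.14, at percentile 0.17 (middle 95% from −0.08 to 0.11), which argues against the general fall of dim genes as the whole cause. Random lists leave out correlation between members, estimated at 0.222, and with it the list had adjusted p = 0.622 at the same median, so whether the list fell beyond other genes is less certain than the percentile alone gives. A smaller share of non-hepatocytes cannot be told apart either: 3 of 4 marker lists had medians above the 25th percentile of random lists of like brightness, but this limit, set before, lies inside the spread of those lists, and the stellate, endothelial and T cell medians were all below 0, at percentiles 27.66, 29.96 and 44.55. The Kupffer markers lay at percentile 0.19, and a fall in that cell type stays open, as does an effect of treatment, untested apart from slide.

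The rise of PXR and CAR responsive genes lay at percentile 100 of random lists of like brightness, and its lowest median with 1 array left out was 1.29, so neither the trend with brightness nor 1 array accounts for it. With an estimated correlation the list had adjusted p = 0.192 at the same median. For the number of lists past the camera test, 6 of 10 splits of the arrays gave as many, the real one with 8 and the highest other with 12, and 10 splits are too few for a share under 0.05. Each other split sets 2 arrays of a group against 1, so part of the treatment difference stays in it, and these counts decide nothing on the lists. With an estimated correlation 0 lists passed. Fry, which does not set a list against other genes, called 10 lists as moving one way and 29 as changing in either direction.

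Hamp, which encodes the iron hormone hepcidin, varied widely: its log2 signal was −2.25 on PCN array 1 against 5.90 and 6.66 on PCN arrays 2 and 3, and 5.72 to 6.08 on the control arrays. The difference of −2.46 ± 2.20 did not pass the test (adjusted p = 0.477).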
